A study of Mus musculus with 42 samples.

How the data were processed

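RNA sequencing of 42 mouse brain libraries was re-analysed, 20 labelled cerebellum and 22 labelled hippocampus, in 4 groups per region label (control or western diet for 12 weeks, with or without NaKtide). The text on the design of the series describes liver and adipose tissue and 60 samples instead, so the tissues and groups rest on the labels of the libraries alone. The submitters' processing notes name Trimmomatic 0.38, HISAT2 2.1.0, DESeq2 1.20.0 and the mouse build GRCm38. The libraries were made with a stranded mRNA kit per the labels, and the read counter and gene annotation are not given in the sources used here. The deposited tables hold 54232 Ensembl genes for each of the 42 libraries, with no value column left without a sample. The first deposited table holds the raw count of each gene. In the second, the authors divided each count by a size factor of its library, so its signal is a normalized count. The raw count over this value was 1 number per library to a relative spread of 6.7e-16, and these factors equalled median-of-ratios factors over all 42 libraries to 2.3e-15. The third deposited table holds FPKM, which the authors computed from the normalized counts with 1 factor per gene (relative spread 9.4e-14). Only the raw counts were used for the results, and the other tables were used to check how they were made.

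Library totals ran from 4669374 to 9521002 counts, with 14665 to 16345 genes of at least 10 counts, and 33562 genes had at least 1 count. Of the counts, 7.27% on average fell in 13 mitochondrial protein genes and 4.06% in 4 mitochondrial pseudogenes. Symbols were found for 54079 gene IDs, and coordinates in GENCODE M21 for 54165.

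Groups were taken from the labels. The libraries of each region label were fitted together, with the 4 groups as 1 factor, by edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F test) in R 4.3.3. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. This tested 16338 genes in libraries labelled cerebellum, 16442 in those labelled hippocampus and 17088 where both were fitted together with 8 groups. The contrasts were the diet with and without NaKtide, NaKtide on each diet, their interaction, the differences of 3 of these between the region labels, and the region labels in control mice. In the descriptions of single libraries, levels of Gabra6, Gh, Hcrt, Ttr, Xist, Capn11 and, in the report, Tph2 are CPM of the library total without TMM factors. Log2 fold changes are those of edgeR, the SE is the fold change over the square root of F, and levels are means and SD of CPM with TMM factors. Gene lists fixed before the data were examined were tested with limma 3.58.1, by camera with its preset correlation of 0.01, camera with an estimated correlation, and fry, adjusted over the lists of a contrast. Beside counts over all genes, members were also counted with p adjusted over the list alone.

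Genes to name were chosen by a rule set before the data were examined. Among called genes with a symbol (not Gm plus digits or ending in Rik) and a mean of at least 1 CPM, these were the 6 largest rises, the 6 largest falls, the 6 smallest p and the 2 smallest p of each list. Where fewer than 10 genes passed, all were named, with the next smallest p up to 10. The text gives some of them. Markers of regions and neighbouring tissues, and Xist, were chosen for the library descriptions after their values were seen.

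The reversal of the diet change was the share of diet-changed genes with the opposite sign under NaKtide on western diet, compared with 80 shuffles of the group labels and with all 20 divisions of the western diet libraries. Label splits were counted in 100 draws per comparison. Alternatives set before the data were examined were DESeq2 size factors in edgeR, DESeq2 1.42.0, no low-count filter, the compared groups only, the replicate number as a block, 2 surrogate variables from sva 3.50.0, and leaving out each library in turn. Chosen after seeing the data were summing hippocampus control 5 and 6, leaving out 4 libraries marked by Xist, offsets for trends with exon length and GC content, the leading component of the libraries of the other label as a covariate, and thinning to the smallest total. Whether replicate numbers pair samples was checked from correlations of same-numbered libraries. Their median was -0.06 in libraries labelled cerebellum, -0.10 in those labelled hippocampus and -0.02 between the labels, so no pairing was used.

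The fit was tested on simulated data with 200 changed genes per comparison. Counts were drawn gene by gene, with no structure shared by many genes of a library. The rates below therefore do not cover differences in tissue content between the real libraries. For NaKtide on western diet in libraries labelled hippocampus it recovered 99% of 4-fold and 57% of 2-fold changes, with 6.6% false calls, and for the diet without NaKtide 98%, 68% and 2.4%. In libraries labelled cerebellum it recovered 97% and 46% for the diet without NaKtide, with 2.7% false, and for the interaction 83% and 21%, with 4.6% false. For the differences between the region labels it recovered 83% to 86% of 4-fold and 31% to 40% of 2-fold changes, with 3.1% to 5.8% false calls, and for the region labels in control mice 94% and 71%, with 7.3% false.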

Results

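Gene expression was measured by RNA sequencing in 42 mouse brain libraries, 20 labelled cerebellum and 22 labelled hippocampus. Each region label held 4 groups, made by 12 weeks on a control diet with 11% fat or a western diet with 42% fat, each with or without NaKtide. NaKtide is a peptide taken from the Na,K-ATPase sodium pump that blocks signalling from the pump to the kinase Src. Per the labels it was expressed from a transgene induced with 300 mg/kg doxycycline, so the transgene and doxycycline went with it, and the labels do not say whether the other mice received doxycycline. The cerebellum label held 5 libraries in each group. The hippocampus label held 6 control, 5 control with NaKtide, 5 western and 6 western with NaKtide libraries. Totals ran from 4669374 to 9521002 counts per library. Between 14665 and 16345 genes per library had at least 10 counts. The labels do not say that the libraries come from separate animals, so p-values measure only the spread between these samples, which can be technical.

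Transcripts that mark brain regions and neighbouring tissues varied widely between libraries of one group. Gabra6, a GABA receptor subunit of cerebellar granule cells, was under 1 CPM (count scaled to library size) in 14 of the 20 libraries labelled cerebellum and at 10 CPM or more in 3 of them. It reached 10 CPM in 1 of the 22 libraries labelled hippocampus. The region names used here are therefore those of the labels. Transcripts of the pituitary hormone gene Gh reached 184 CPM in cerebellum control 1 and 447 CPM in hippocampus control NaKtide 4. The hypothalamic neuropeptide gene Hcrt reached 354 CPM in cerebellum control 4, and Tph2, an enzyme of serotonin neurons, reached 275 CPM in cerebellum control 2. Ttr, the abundant transcript of the choroid plexus, ranged from 6.13 to 5184 CPM over the libraries labelled hippocampus. Hippocampus control 5 and 6 were the closest pair of libraries, with a mean chi-square of 2.45 per gene against 7.69 for the next pair within a group. Cerebellum western NaKtide 5 came next, at 3.67 from hippocampus control 6 and 5.87 from control 5, across the region labels. Between hippocampus control 5 and 6, 11.4% of genes differed at an unadjusted p under 0.05, which does not show separate samples, since repeated libraries of 1 RNA can differ as well. They were counted as 2 libraries, as labelled, and summed into 1 as an alternative. Hippocampus western NaKtide 6 held 162 CPM of Xist, the transcript of the inactive X chromosome, and 0.2 CPM in sum of 4 Y-linked genes, whereas 38 other libraries held 0 to 5 counts of Xist. Xist was also present beside Y-linked transcripts at 11.4 CPM in hippocampus control 5, 9.90 CPM in hippocampus control 6 and 38.4 CPM in cerebellum western NaKtide 5.

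**Figure D1:**
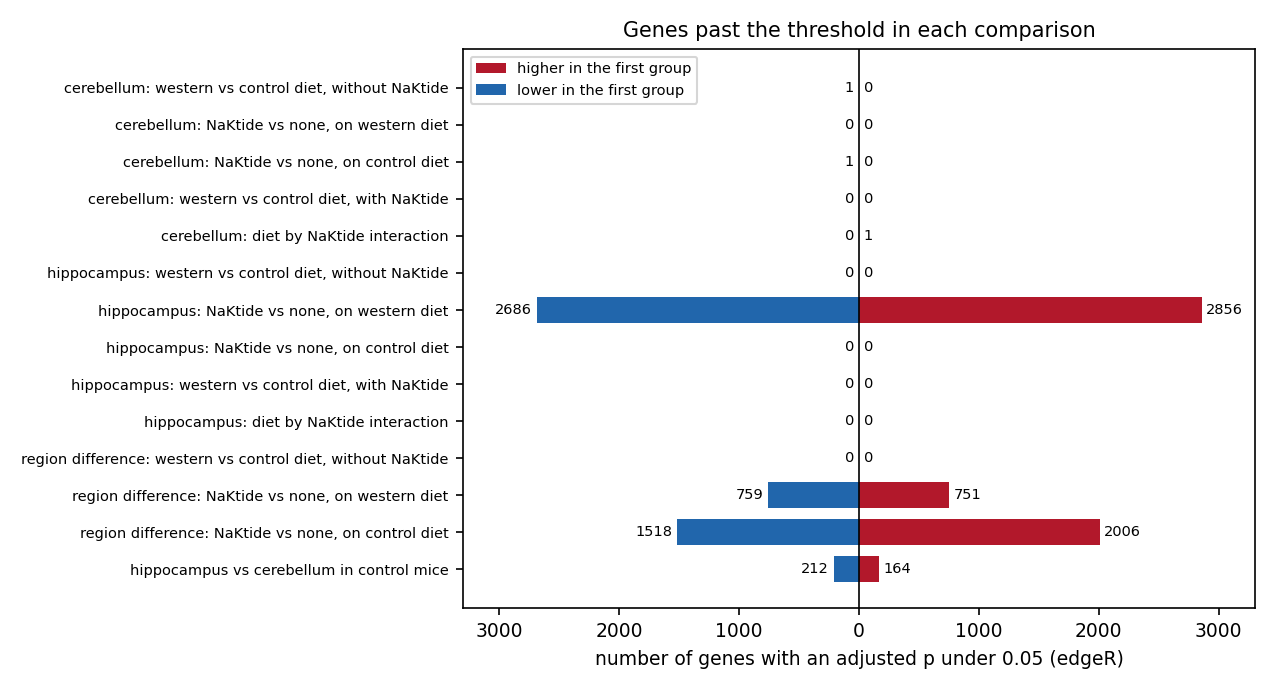
Number of genes with an adjusted p under 0.05 in edgeR for each of 14 comparisons, drawn to the right for genes higher and to the left for genes lower in the first group named. The largest count is NaKtide against none on western diet in libraries labelled hippocampus, with 2856 genes higher and 2686 lower, while the other comparisons within a region label called 0 or 1 gene.

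The first question was whether NaKtide changed expression in mice on the western diet. In libraries labelled hippocampus, western diet with NaKtide (n = 6) differed from western diet alone (n = 5) in 5542 of 16442 genes by edgeR, 33.7% of those tested, with 2856 higher and 2686 lower. Aif1, a calcium-binding protein of microglia (ENSMUSG00000024397, GRCm38 chromosome 17, 35170991 to 35176068), rose from 5.28 ± 1.18 to 16.6 ± 2.66 CPM (mean ± SD), a log2 fold change of 1.64 (SE 0.22, adjusted p = 0.000907). Elovl4, an elongase of very long chain fatty acids (ENSMUSG00000032262, chromosome 9, 83778692 to 83806277), fell from 47.4 ± 3.86 to 25.2 ± 0.76 CPM, a log2 change of -0.91 (SE 0.12). Falls of the same adjusted p were seen in Mosmo, a regulator of hedgehog signalling, with a log2 change of -1.37 (SE 0.19), in the calcium pump gene Atp2b3 with -1.92 (SE 0.27), and in Fgd4, an exchange factor for Cdc42, with -1.81 (SE 0.25). Each of these 5 genes moved in its direction in 6 of 6 NaKtide libraries. Among the largest falls were Lct, a marker of dentate granule cells, at 0.74 ± 0.90 against 22.4 ± 26.0 CPM (adjusted p = 0.00905), and the ion exchanger gene Slc9a4, at 0.37 ± 0.86 against 5.57 ± 3.49 CPM (adjusted p = 0.00809). Among the largest rises, Ptprv, a receptor-type phosphatase, averaged 5.39 against 0.26 CPM (log2 change 4.25, SE 1.04) and was higher in 5 of 6 NaKtide libraries (adjusted p = 0.00603). DESeq2 called 6072 genes in the same comparison. The count was 5591 without the 4 libraries marked by Xist, a test chosen after seeing the data.

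**Figure D2:**
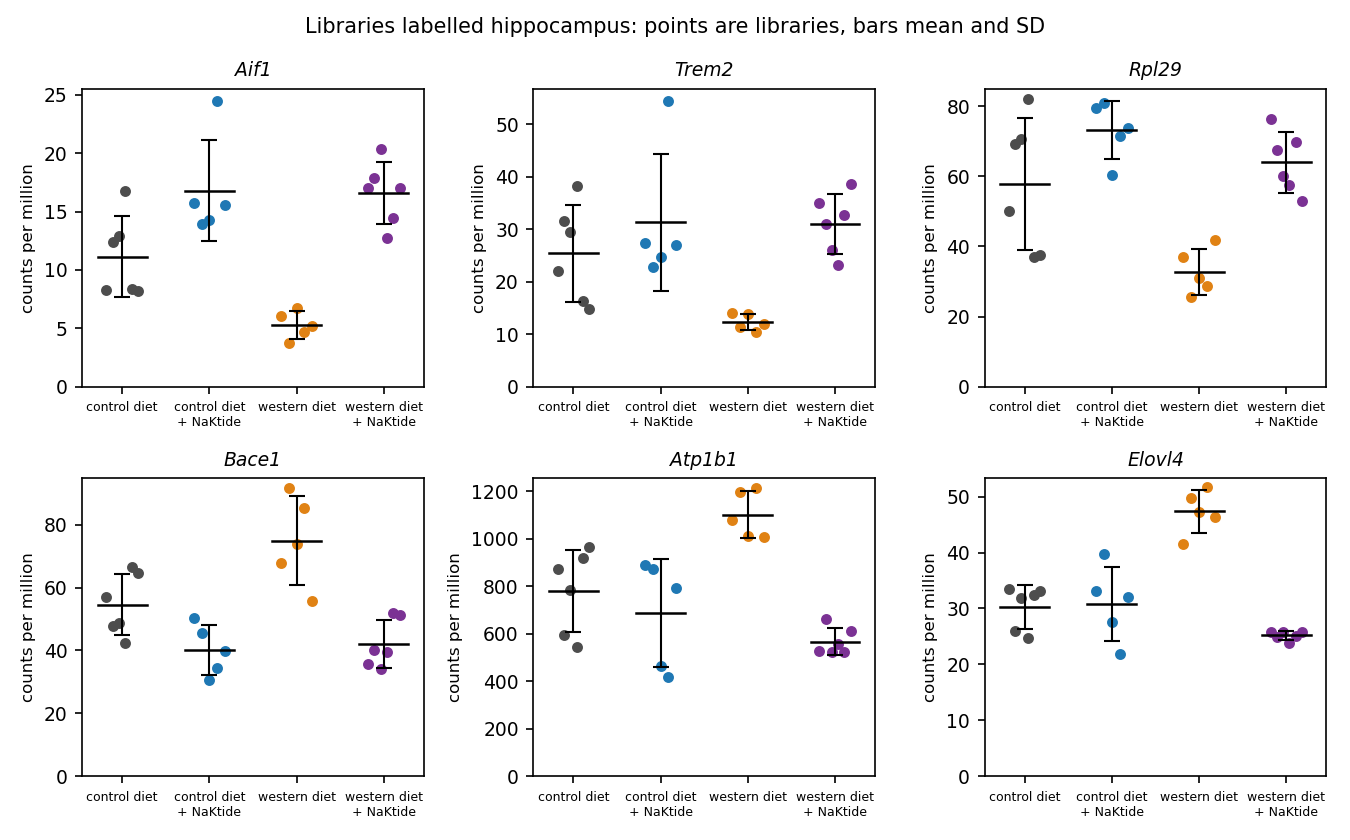
Levels in CPM of 6 genes in each library labelled hippocampus, by diet and NaKtide. Points are libraries, and bars give the mean and SD of the 5 or 6 libraries of a group. Aif1 averaged 5.28 CPM on western diet alone and 16.6 CPM with NaKtide, and Elovl4 averaged 47.4 and 25.2 CPM.

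Most ribosomal protein genes and many respiratory chain genes rose in this comparison. Of 76 cytosolic ribosomal protein genes, 72 rose and 0 fell, and 76 rose when adjusted over the list alone, with a median log2 change of 0.90. Rpl29, a protein of the large ribosomal subunit, rose from 32.8 ± 6.63 to 64.0 ± 8.68 CPM (log2 change 0.97, SE 0.19, adjusted p = 0.00258). Of 70 nuclear-encoded genes of the respiratory chain, 45 rose and 2 fell, against 56 and 3 adjusted over the list alone, with a median of 0.63. Uqcrq, a subunit of complex III, rose by 0.84 (SE 0.21, adjusted p = 0.00688). Of the 13 mitochondrially encoded genes 3 rose, among them mt-Co1, a subunit of cytochrome c oxidase, by 0.95 (SE 0.27, adjusted p = 0.0116). Counts in mitochondrial protein genes were 15.6%, 11.1% and 8.92% of western NaKtide 3, 1 and 4, against at most 5.98% of the other 3 and 4.85% to 7.29% of the western libraries without NaKtide. Camera with its preset correlation called these lists at adjusted p = 7.14e-23, 2.48e-11 and 0.0411, and with an estimated correlation the values were adjusted p = 0.772, 0.876 and 0.876. Fry, which tests whether a list moves one way, gave 0.00833, 0.0286 and 0.212. Of the 37 lists tested in this comparison, fry called 9, camera with its preset correlation 7 and camera with an estimated correlation 0. Across genes, which are not independent replicates, the fold change fell with exon length (r = -0.40) and rose with GC content (r = 0.38), and its median was 0.48 in the lowest quartile of length and -0.28 in the highest. With a trend of each library against exon length and GC taken out, an alternative chosen after seeing the data, 68 ribosomal and 25 respiratory chain genes rose.

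Of the microglia markers 10 of 20, and of the antioxidant genes 10 of 30, were higher with NaKtide on the western diet. Of all genes tested 33.7% were called there, higher or lower. Of 20 microglia markers, 10 rose and 0 fell, against 11 and 1 adjusted over the list alone, with a median log2 change of 0.49 (camera adjusted p = 0.000387, and adjusted p = 0.772 with an estimated correlation). Beside Aif1 these included Trem2, a lipid receptor of microglia, which rose from 12.4 ± 1.53 to 31.1 ± 5.68 CPM (log2 change 1.33, SE 0.25, adjusted p = 0.00185) in 6 of 6 libraries. With the length and GC trend taken out 9 microglia markers rose. Of 30 antioxidant and NRF2 target genes, 10 rose and 1 fell, with the same counts adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.109). Gpx1, a glutathione peroxidase, rose by 0.89 (SE 0.20, adjusted p = 0.00405), and Sod1, the cytosolic superoxide dismutase, by 0.77 (SE 0.20, adjusted p = 0.00867). Of 20 interferon response and MHC class I genes 5 rose, or 1 adjusted over the list alone, among them the proteasome subunit gene Psmb8 from 3.32 ± 1.18 to 7.69 ± 2.91 CPM (adjusted p = 0.00951), and that list was not called either (camera adjusted p = 0.0699). In the cytokine and NF-kB list 3 of 16 genes rose and 2 fell, and the inflammasome cytokine gene Il18 rose by 0.96 (SE 0.21, adjusted p = 0.00381). As 33.7% of all genes tested were called in this comparison, these counts do not set the antioxidant, interferon and cytokine lists apart. Hemoglobin and heme synthesis transcripts moved with these groups, as 4 of 5 blood cell markers rose, with a median of 1.15 (camera adjusted p = 0.0827), and 0 of them passed with the length and GC trend taken out.

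Part of the genes of insulin signalling and synapses were lower with NaKtide. Of 20 insulin and leptin signalling genes, 8 fell and 0 rose, with the same counts adjusted over the list alone and a median log2 change of -0.30 (camera adjusted p = 0.0226, and adjusted p = 0.772 with an estimated correlation). Irs1, an adaptor of the insulin receptor (ENSMUSG00000055980, chromosome 1, 82233101 to 82291416), went from 4.50 ± 1.53 to 0.80 ± 0.43 CPM, a log2 change of -2.51 (SE 0.41, adjusted p = 0.00117), lower in 6 of 6 libraries. Of 24 synaptic and plasticity genes 13 fell and 0 rose, also adjusted over the list alone, with a median of -0.61 (camera adjusted p = 7.86e-05, and adjusted p = 0.772 with an estimated correlation). With the length and GC trend taken out, 6 insulin and leptin genes fell, and 3 synaptic genes fell and 1 rose. In the list for the target of the peptide, Na,K-ATPase and Src signalling, 5 of 21 genes fell and 1 rose, and the list was not called (camera adjusted p = 0.335). Atp1b1, the pump's beta subunit (ENSMUSG00000026576, chromosome 1, 164437109 to 164458355), fell from 1102 ± 99.7 to 567 ± 58.4 CPM (log2 change -0.96, SE 0.19, adjusted p = 0.00244), and Hras, a small GTPase, rose by 0.72 (SE 0.17, adjusted p = 0.00521). Of 21 Alzheimer disease-related genes 6 fell and 3 rose, or 8 and 4 adjusted over the list alone, and Bace1, the beta-secretase that cleaves the amyloid precursor, changed by -0.83 (SE 0.16, adjusted p = 0.00244). The cholesterol synthesis list went both ways, with 4 of 25 genes higher and 5 lower, such as Pmvk at 0.90 (SE 0.23, adjusted p = 0.00719) and Hsd17b7 at -1.08 (SE 0.24, adjusted p = 0.00419). Of all genes tested 33.7% were called in this comparison. The counts in the Na,K-ATPase, Alzheimer and cholesterol lists are near or below that share and do not set these lists apart.

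Some markers of hippocampal cell types and of the striatum passed in the same comparison. Of 9 dentate granule cell markers 4 fell, or 6 adjusted over the list alone, with a median log2 change of -1.64 (camera adjusted p = 0.00777, and adjusted p = 0.772 with an estimated correlation), and Stxbp6 among them changed by -1.42 (SE 0.24, adjusted p = 0.00123). Of 11 hippocampal pyramidal cell markers 2 fell, among them the transcription factor gene Neurod6, at 12.2 ± 12.8 against 103 ± 49.8 CPM (adjusted p = 0.00471). As 33.7% of all genes tested were called, that count does not set the pyramidal cell list apart. Of 10 striatum markers 5 rose, or 8 adjusted over the list alone, with a median of 2.35 (camera adjusted p = 0.0699). Rgs9, a regulator of G protein signalling in striatal neurons, averaged 112 CPM with NaKtide (SD 128), a log2 change of 3.11 (SE 0.95, adjusted p = 0.0171). Without the 4 libraries marked by Xist, which include western NaKtide 6, 0 striatum markers passed. Marker scores (mean log2 of CPM plus 1 over the markers) varied between the libraries. With NaKtide the striatum score ran from 3.63 to 8.32, highest in western NaKtide 6. The thalamus score ran from 3.19 to 6.68, highest in western NaKtide 3. On western diet alone these ran from 3.24 to 5.03 and from 3.07 to 5.83. The pyramidal cell score ran from 3.03 to 4.43 with NaKtide and from 4.35 to 5.44 without. With the leading component of the libraries labelled cerebellum as a covariate, also chosen after seeing the data, 2076 genes were called in all, 1815 of them among the 5542, including 30 ribosomal, 5 respiratory chain and 7 microglia genes that rose.

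**Figure D3:**
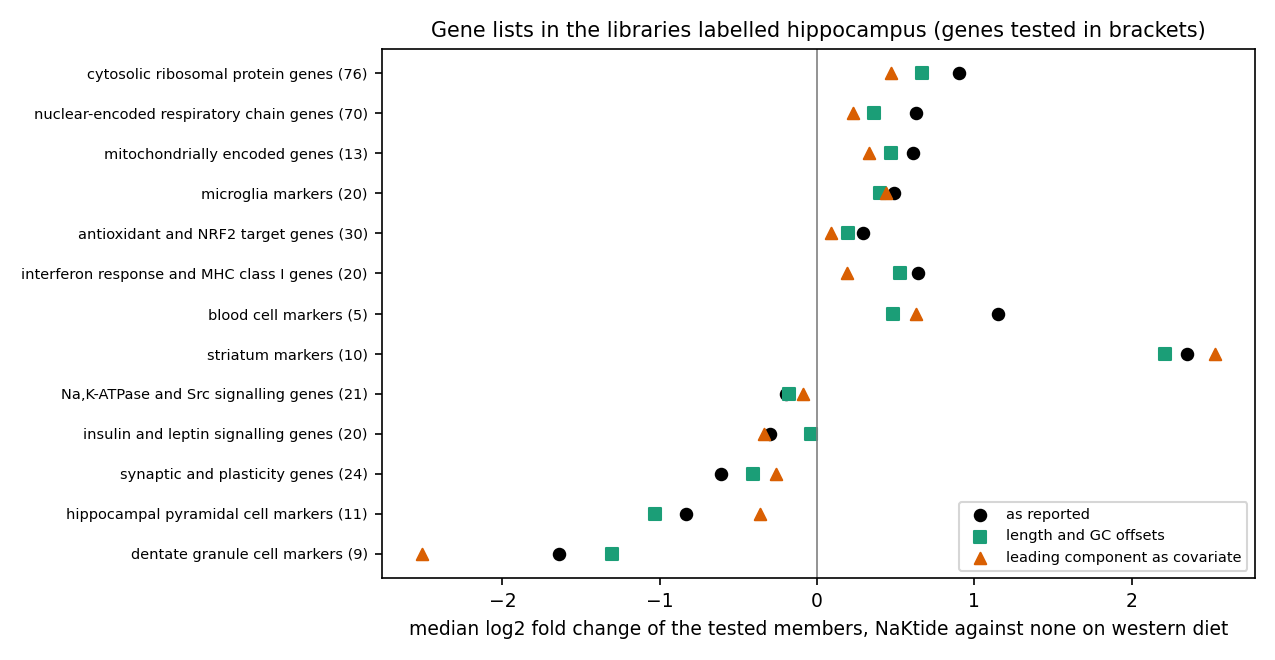
Median log2 fold change of the tested members of 13 gene lists, NaKtide against none on western diet in libraries labelled hippocampus, with the number of genes in brackets. Circles are the reported values, squares those with exon length and GC trends taken out and triangles those with the leading component of the libraries labelled cerebellum as a covariate. The ribosomal median was 0.90 as reported and 0.67 and 0.47 under the alternatives.

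Whether the western diet itself changed expression was asked in mice without NaKtide. In libraries labelled hippocampus, Luzp1, a cytoskeletal leucine zipper protein, stood at 83.1 ± 11.4 CPM on western diet (n = 5) and 45.3 ± 2.79 CPM on control diet (n = 6), a log2 difference of 0.87 (SE 0.15, adjusted p = 0.0602). Elovl4 stood at 47.4 ± 3.86 and 30.3 ± 3.87 CPM (log2 difference 0.65, SE 0.12, adjusted p = 0.0602), and the calmodulin-binding transcription factor gene Camta1 at 277 ± 22.6 and 149 ± 32.8 CPM (0.90, SE 0.16, adjusted p = 0.0602). None of these passed, and edgeR called 0 of 16442 genes, with 4046 at an unadjusted p under 0.05, whereas DESeq2 called 825 (535 higher, 290 lower). The ribosomal list had a median of -0.57 (camera adjusted p = 1.51e-19, and adjusted p = 0.838 with an estimated correlation), and 60 of its 76 genes were lower adjusted over the list alone, against 0 over all genes tested. The microglia list had a median of -0.39 (camera adjusted p = 6.27e-06), with 7 genes lower adjusted over the list alone, and the striatum list -2.41 (camera adjusted p = 0.000244), with 9 lower, and both had adjusted p = 0.838 with an estimated correlation. The fold change rose with exon length across genes (r = 0.40). The count was 28 without control 5, 515 without control 6, 345 without western 5, and 39 with control 5 and 6 summed into 1 library. It was 2953 with 2 surrogate variables, 2209 without the 4 libraries marked by Xist and 1015 with the component covariate, and in these 73, 28 and 28 ribosomal genes were lower.

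NaKtide was then compared with the diet change to ask whether it moved diet-changed genes back. Because fewer than 20 genes passed for the diet by edgeR, the 200 genes with its smallest p were used (DESeq2 called 825 in libraries labelled hippocampus and 142 in those labelled cerebellum), and the shared western diet libraries favour opposite signs. In libraries labelled hippocampus 200 of 200 such genes changed in the opposite direction with NaKtide, a share of 100%. With the group labels of all libraries shuffled 80 times the share had a median of 95% and was as high in 8 of 80. The covariance of the fold changes across genes was -0.295, against a median of -0.0729 in the shuffled groups (95% range -0.173 to -0.0116), a difference of -0.222. With the western diet libraries divided between the comparisons, in each of 20 ways, the share averaged 95% (77% to 99.5%). The division cannot tell a reversal from any other difference of the western libraries as a group, technical ones included, which both parts would carry. The trend of the fold change with exon length was also opposite, at r = 0.40 for the diet and -0.40 for NaKtide. In libraries labelled cerebellum the share was 176 of 200, 88%, below the shuffled median of 93.5%, and it averaged 48.9% with the western diet libraries divided. Leaving out cerebellum western NaKtide 3 gave 66%, western NaKtide 2 gave 82.5%, control 5 gave 70.7% and western 1 gave 93.5%.

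The effect of NaKtide without the western diet was examined next. In libraries labelled hippocampus on control diet, the pituitary hormone gene Gh stood at 194 ± 260 CPM with NaKtide (n = 5) and 0.59 ± 0.73 CPM without (n = 6), carried by control NaKtide 3 and 4 (adjusted p = 0.0551). The RNA-binding protein gene Lsm8 stood at 24.9 ± 3.46 and 16.3 ± 2.36 CPM, a log2 difference of 0.61 (SE 0.14, adjusted p = 0.210). EdgeR called 0 genes, with 2720 at an unadjusted p under 0.05, and DESeq2 called 12. The ribosomal list had a median of 0.66, with 68 of 76 genes higher adjusted over the list alone and 0 over all genes (camera adjusted p = 1.35e-31, and adjusted p = 0.857 with an estimated correlation), and the respiratory chain list 0.46, with 25 of 70 higher (camera adjusted p = 8.95e-18, and adjusted p = 0.857 with an estimated correlation). The choroid plexus list had a median of 0.81 (camera adjusted p = 0.0107, and adjusted p = 0.867 with an estimated correlation), and the fold change fell with exon length (r = -0.39). Leaving out control NaKtide 1, 2 or 5 in turn each gave 1 call.

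The diet in mice with NaKtide, and the interaction of diet and NaKtide, completed the comparisons in libraries labelled hippocampus. Western diet with NaKtide (n = 6) against control diet with NaKtide (n = 5) gave 0 genes by edgeR, with 1756 at an unadjusted p under 0.05 and 33 by DESeq2. Gh differed by a log2 value of -7.22 (SE 1.24, adjusted p = 0.0831), and Lsm8 by -0.80 (SE 0.14, adjusted p = 0.0831). The choroid plexus list had a median of -1.28 (camera adjusted p = 2.92e-06) and the ependymal list -1.36 (camera adjusted p = 0.000138), both with adjusted p = 0.830 with an estimated correlation. Without western NaKtide 2, which held 4966 CPM of Ttr, 6 genes were called, and without control NaKtide 1 or 5 in turn 1 gene. The interaction also gave 0 genes by edgeR, with 2399 at an unadjusted p under 0.05 and 183 by DESeq2, so the response to NaKtide was not shown to differ between diets at this threshold. Its smallest adjusted p was shared by genes such as Elovl4 (-0.94, SE 0.18), Camta1 (-1.18, SE 0.23) and the imprinted gene Rtl1 (3.13, SE 0.61), at 0.0823. Its striatum list had 10 of 10 genes higher adjusted over the list alone (camera adjusted p = 7.71e-07, and adjusted p = 0.648 with an estimated correlation), and its microglia list 0.49, with 8 of 20 higher (camera adjusted p = 1.21e-07, and adjusted p = 0.580 with an estimated correlation). Leaving out control NaKtide 4 gave 47 calls, control NaKtide 5 gave 3 and western NaKtide 2 gave 59.

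In libraries labelled cerebellum edgeR with all libraries called 1 gene in each comparison with the control mice. Capn11, a calpain protease best known from testis (ENSMUSG00000058626, chromosome 17, 45630204 to 45659325), stood at 11.9 ± 1.91 CPM in controls (n = 5) and 0.41 ± 0.31 CPM on western diet (n = 5), a log2 change of -4.79 (SE 0.47, adjusted p = 4.39e-05), lower in 5 of 5 libraries. It was the 1 gene of 16338 called by edgeR for the diet without NaKtide, with 3192 at an unadjusted p under 0.05, and DESeq2 called 142. It was likewise lower with NaKtide on control diet, at 0.98 ± 0.65 CPM (log2 change -3.59, SE 0.42, adjusted p = 0.000823), again the 1 gene called by edgeR, with 4816 at an unadjusted p under 0.05 and 1346 by DESeq2. The interaction of diet and NaKtide called Capn11 as well (log2 value 5.16, SE 0.64, adjusted p = 0.00218), with 2844 at an unadjusted p under 0.05 and 17 genes by DESeq2, and 0 genes with all libraries thinned to equal totals. These calls of Capn11 all rest on the same 5 control libraries and are not independent. Controls labelled hippocampus averaged 0.79 CPM without TMM factors, so control diet alone did not go with a high level. What set the cerebellum controls apart was not tested. Pomc, the precursor of pituitary and hypothalamic peptides, stood at 38.2 ± 41.1 CPM in controls, 2.44 ± 0.70 on western diet (adjusted p = 0.148) and 1.99 ± 0.84 with NaKtide on control diet (adjusted p = 0.0751). The diet count was 841 without control 5 and 2 without control 3. The count for NaKtide on control diet was 4386 without control 5, and 2 without control 3 or control NaKtide 1, and the interaction count was 5 without control 5.

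**Figure D4:**
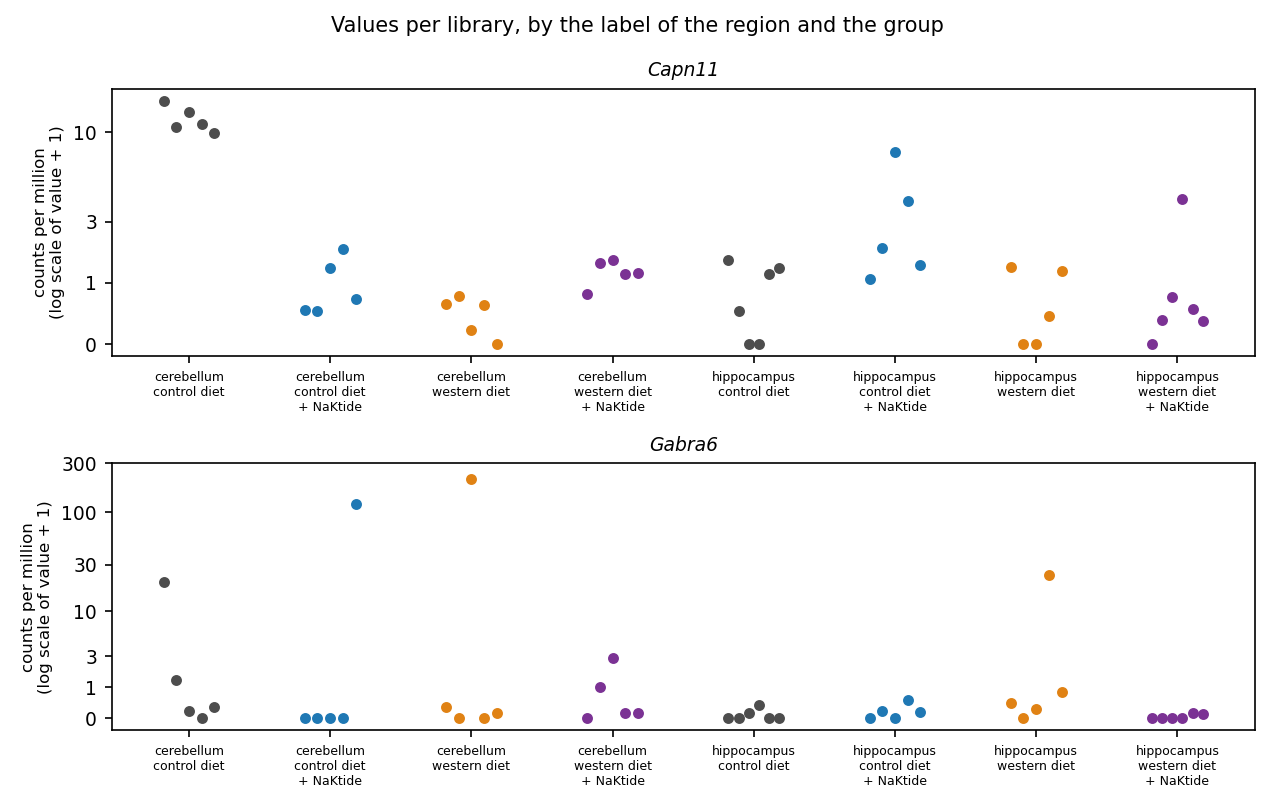
Capn11 and Gabra6 in each of the 42 libraries, in CPM on a log scale of the value plus 1, by the label of the region and the group. Capn11 averaged 11.9 CPM in the 5 cerebellum control libraries, and Gabra6 was under 1 CPM in 14 of the 20 libraries labelled cerebellum.

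In both comparisons with the control group, camera with its preset correlation called gene lists in libraries labelled cerebellum, 10 for the diet and 12 for NaKtide of 39, whereas fry and camera with an estimated correlation called 0. On western diet the ribosomal list had a median log2 difference of -0.67, with 65 of 76 genes lower adjusted over the list alone and 0 over all genes (camera adjusted p = 9.87e-28, and adjusted p = 0.900 with an estimated correlation). The 13 mitochondrially encoded genes had a median of -0.71, and 13 were lower adjusted over the list alone (camera adjusted p = 2.55e-11, and adjusted p = 0.900 with an estimated correlation). Immediate-early genes, which respond to neuronal activity, had a median of 1.14 with 9 of 18 higher adjusted over the list alone (camera adjusted p = 5.50e-06), and circadian clock genes 0.50 with 8 of 17 higher (camera adjusted p = 2.11e-05), each with adjusted p = 0.900 with an estimated correlation. With NaKtide on control diet the ribosomal median was -0.71 with 72 lower, the respiratory chain median -0.58 with 51 of 70 lower, and the oligodendrocyte and myelin median -1.20 with 16 of 16 lower, each adjusted over the list alone (camera adjusted p = 6.82e-23, 2.98e-17 and 2.02e-07, and adjusted p = 0.648 with an estimated correlation for each). The 5 blood cell markers had a median of -1.75, and 5 were lower adjusted over the list alone (camera adjusted p = 0.00259, and adjusted p = 0.648 with an estimated correlation). Beside these lists, cell type markers on western diet had medians of 1.59 for cerebellar granule cells, 1.53 for Purkinje cells, -1.37 for brainstem, -0.90 for ependymal cells and -0.70 for oligodendrocytes. The sign changed in 1 of 10 alternatives for granule cells, Purkinje cells and oligodendrocytes and in 2 of 9 for brainstem. Single omissions were not among these alternatives. Cerebellum western 3 scored 7.95 for granule cells and 8.95 for Purkinje cells (mean log2 of CPM plus 1 over the markers). By group, the median scores were 3 and 4.79 on western diet and 2.7 and 4.8 in controls. With NaKtide on control diet the marker medians were -3.65 for brainstem, -1.42 for choroid plexus, -1.35 for ependymal cells, 1.41 for striatum and 1.02 for dentate granule cells. Each kept its sign in the alternatives counted, which again left out single omissions, and this says nothing of their size. Brainstem scores were 2.06 and 2.55 in control 1 and 2 and 0.21 to 0.27 in the other controls. Their median was 0.27 in controls, 0.85 on western diet and 0.32 with NaKtide on control diet. The fold change rose with exon length across genes for the diet (r = 0.39) and for NaKtide (r = 0.33). With the length and GC trend taken out the ribosomal median was -0.51 for the diet and -0.55 for NaKtide, and with 2 surrogate variables as covariates it was -0.02 and 0.

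The comparisons within western diet and within NaKtide gave few or no calls in libraries labelled cerebellum, 0 by edgeR and 1 by DESeq2 in each. For NaKtide on western diet (n = 5 and 5) the cadherin gene Celsr3 stood at 33.6 ± 7.20 against 71.2 ± 36.6 CPM (log2 difference -1.08, SE 0.28, adjusted p = 1), and edgeR called 0 genes, with 679 at an unadjusted p under 0.05 and 1 by DESeq2. The striatum list had a median of 1.30 and the microglia list 0.25 (camera adjusted p = 7.78e-06 for each, and adjusted p = 0.786 with an estimated correlation). Other marker medians were -1.69 for cerebellar granule cells and -1.41 for Purkinje cells, each with the other sign in 1 of 10 alternatives (single omissions not counted), and 1.42 for brainstem and -0.87 for thalamus. Cerebellum western 3 held 225.17 CPM of Gabra6, against 0 to 0.29 CPM in the other western libraries without NaKtide. By group, the median granule cell score was 3.31 with NaKtide and 3 without, and the Purkinje cell score 4.67 and 4.79. The median brainstem score was 0.45 with NaKtide and 0.85 without, against the sign of the marker median. It was highest in western NaKtide 2, at 3.41. For the diet in mice with NaKtide (n = 5 and 5) the hypothalamic transcription factor gene Otp stood at 6.34 ± 7.09 against 0.22 ± 0.27 CPM (adjusted p = 0.999), and edgeR called 0 genes, with 396 at an unadjusted p under 0.05 and 1 by DESeq2. The oligodendrocyte and myelin list had a median of 0.86 (camera adjusted p = 4.64e-19, and adjusted p = 0.372 with an estimated correlation), and 3 of 5 brainstem markers were higher adjusted over the list alone. Brainstem scores with NaKtide ran from 0.28 to 3.41 on western diet (median 0.45) and from 0.09 to 0.43 on control diet (median 0.32). Leaving out cerebellum western 1 gave 1 call for NaKtide on western diet.

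The test of the difference between the region labels asked where responses to NaKtide or diet diverged. On western diet, the response to NaKtide differed between the labels in 1510 of 17088 genes by edgeR, 751 more positive in hippocampus and 759 more negative. Mosmo differed by a log2 value of -1.87 (SE 0.33) and the flippase subunit gene Tmem30a by -1.92 (SE 0.36), both with adjusted p = 0.0140, while Irs1 differed by -2.69 (SE 0.67, adjusted p = 0.0162) and Aif1 by 1.41 (SE 0.36, adjusted p = 0.0176). On control diet the response differed in 3524 genes, 2006 more positive and 1518 more negative, among them Gh (12.29, SE 1.82, adjusted p = 0.000717), Pomc (5.85, SE 0.88, adjusted p = 0.000717) and the actin-severing protein gene Dstn (0.96, SE 0.17, adjusted p = 0.00450). Gh and Pomc were uneven within groups, in CPM without TMM factors. In cerebellum controls Gh ran from 2.85 to 184.2 CPM and Pomc from 3.39 to 95.05 CPM. In hippocampus control NaKtide 3 and 4 Gh was 388.22 and 447.17 CPM, against 0.75 to 11.96 CPM in the rest of that group. On control diet 75 of 76 ribosomal genes were more positive, with a median of 1.39 (camera adjusted p = 2.71e-32, and adjusted p = 0.765 with an estimated correlation), and the difference fell with exon length (r = -0.40). Of 39 lists tested there, fry called 8 and camera with an estimated correlation 0. The diet response without NaKtide differed in 0 genes by edgeR, with 907 at an unadjusted p under 0.05 and 1 by DESeq2. The western diet count ran from 416 without cerebellum western NaKtide 4 to 4089 without cerebellum western NaKtide 3, and 12 of 21 omissions moved it by over 1.5 times. The control diet count was 503 without the 4 libraries marked by Xist, and ran from 2020 without cerebellum control NaKtide 5 to 5718 without cerebellum control 5.

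The labels of the regions were compared directly in control mice without NaKtide. Libraries labelled hippocampus (n = 6) differed from those labelled cerebellum (n = 5) in 376 of 17088 genes by edgeR, 164 higher and 212 lower. With hippocampus control 5 and 6, which may hold the same RNA, summed into 1 library, 5 genes were called. Of 18 immediate-early genes 5 were higher over all genes and 15 adjusted over the list alone, with a median log2 difference of 1.94 (camera adjusted p = 8.62e-11, and adjusted p = 0.642 with an estimated correlation), such as Fos at 28.4 ± 18.7 against 5.09 ± 2.39 CPM (adjusted p = 0.0353). Lower genes included Pomc (-3.70, SE 0.60, adjusted p = 0.00596), Capn11 (-3.89, SE 0.72, adjusted p = 0.0134) and the phocein gene Mob4 (-0.74, SE 0.13, adjusted p = 0.0121). Of the 36 called genes that the naming rule gave here, 0 kept their call in every alternative. Among 39 gene lists, fry called 5, camera with its preset correlation 13 and camera with an estimated correlation 0. Of 5 blood cell markers 4 were lower, or 5 adjusted over the list alone, with a median of -1.77 (camera adjusted p = 0.000264, and adjusted p = 0.642 with an estimated correlation). The count ranged from 1 without cerebellum control 2 to 4334 without cerebellum control 5, each of the 11 omissions moved it by over 1.5 times, and DESeq2 called 1709.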

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

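The tests of the Gabra6 and Xist patterns, and the label splits within libraries labelled cerebellum, were chosen after the results they test were seen. Single libraries far from the rest of their group were sought with Dixon's criterion in groups of 5 or 6. Chance meets it in about 1 in 20 groups of normally distributed values, a rate that does not hold for skewed CPM near 0. It flagged 16 of 60 library measures and 17 of 72 pairs of gene and group, so a flag describes a library and does not exclude chance. Gabra6 stood apart in cerebellum control 1 (19.01 CPM), control NaKtide 5 (132.72) and western 3 (225.17), and in hippocampus western 4 (25.13), where the Purkinje cell gene Pcp2 was also apart (71.93). The pituitary hormone gene Gh stood apart in cerebellum control NaKtide 1 (21.43) and hippocampus western NaKtide 2 (5.91). The hypothalamic gene Hcrt did so in cerebellum control 4 (354.36) and western 1 (1.62) and in hippocampus western NaKtide 1 (26.38), and the neuropeptide gene Avp in hippocampus western 1 (2.41) and western NaKtide 1 (65.18). The choroid plexus gene Ttr stood apart in cerebellum control NaKtide 3 (619.16) and western 5 (1726.18) and in hippocampus western 1 (2608.06) and western NaKtide 2 (4966.06). Serotonin and brainstem genes stood apart in cerebellum control 2, in CPM with TMM factors: Tph2 (310.08), Slc6a4 (160.77), Slc6a5 (50.23) and Fev (34.01). Hippocampus western NaKtide 6 stood apart in Xist (162.48), Gpx6 (9.53), Dgkg (9.73), Ido1 (26.44) and Lhx8 (10.22), and cerebellum western NaKtide 5 in Xist (38.36). Others were Capn11 in hippocampus western NaKtide 4 (4.04), Slc9a4 (2.13) and Dsp (5.24) in western NaKtide 2, Gpx6 (0.13) in western 1, Gbx1 (0) in western 5, Junb (166.16) in control 1 and En1 (0.12) in control 5. Gpx6 in western 1, Gbx1 in western 5 and En1 in control 5 lay near the floor. The rest of these groups held 0 to 0.15 CPM of those genes.

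Some effects differed between groups by a test of the difference. The response to NaKtide differed between the region labels in 1510 genes on western diet, and 2 of 100 label splits gave as many, the highest other being 2229. On control diet it differed in 3524 genes, and 1 of 100 splits, the real one, gave as many, the highest other being 2257. In libraries labelled cerebellum the interaction of diet and NaKtide called 1 gene, Capn11, as many as in 2 of 100 splits, the highest other being 4613. The splits exchanged libraries with and without NaKtide within each region label, or for the interaction within each diet. They therefore stand for no response to NaKtide, not for an equal response in both parts. A small share thus does not test the difference itself. These shares are below 0.05 only without adjustment over the 14 comparisons, and splits that call as many as 4613 genes point to a structure of the samples other than their groups.

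Other splits were counted for the remaining comparisons. In libraries labelled hippocampus 1 of 100 splits, the real one, reached the 5542 genes of NaKtide on western diet, and the highest other gave 4037. How many libraries that split shares with the real groups was not examined, so its count cannot tell the real difference from another structure of the samples. In libraries labelled cerebellum 4 of 100 splits gave at least the 1 gene of the diet without NaKtide (highest other 1019), and 3 of 100 at least the 1 gene of NaKtide on control diet (highest other 5771). For the region labels in control mice 3 of 100 reached 376 genes (highest other 6267). These 4 shares too are below 0.05 only without adjustment over the 14 comparisons, and those for the region labels count hippocampus control 5 and 6 as separate libraries. Where the real count was 0 by edgeR, 100 of 100 splits gave as many by construction, so that count says nothing about chance. The highest others there were 1 for NaKtide on western diet and 2 for the diet with NaKtide in libraries labelled cerebellum. In libraries labelled hippocampus they were 1 for the diet without NaKtide, 2737 for NaKtide on control diet, 701 for the diet with NaKtide and 1266 for the interaction, and 2156 for the difference of the diet response between the labels.

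The first pattern weighed was the 5542 genes that differed with NaKtide on western diet in libraries labelled hippocampus. Library depth is argued against by 4342 calls with all libraries thinned to the smallest total (78.3% as many), and a trend with gene length and GC as the whole cause by 3633 calls with that trend taken out (65.6% as many). Different brain pieces in the libraries remain open and cannot be told apart from NaKtide here: the fold change correlated at 0.39 across genes with the leading component of the libraries labelled cerebellum, and 2076 calls were left with that component as a covariate (37.5% as many). In an exact permutation test over all 462 splits, the mean difference correlated with the component at 0.46 and as strongly in 158 splits (exact p = 0.342, highest other 0.81), and the library scores differed as much in 33 (exact p = 0.0714). An effect of NaKtide, its transgene or doxycycline stays open as the biological explanation.

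The second pattern was the near absence of Gabra6 from 14 of 20 libraries labelled cerebellum. Library depth is argued against, since 14 of these 14 had more counts than the median of the libraries at 10 CPM or more. An exchange of cerebellum and hippocampus labels is argued against, since only 1 library labelled hippocampus reached 10 CPM. Tissue from other brain regions is a candidate explanation that the test could not decide. Of the 14, 14 had a striatum or neocortex marker score at or above the lower quartile of the libraries labelled hippocampus. Most libraries meet that bar, since 1 of the scores is enough. Cerebellum control NaKtide 5, with 132.72 CPM of Gabra6, met it as well (striatum 4.31, neocortex 4.11). Outside that test, cerebellum control NaKtide 2 and western NaKtide 1 held 0 CPM of Gabra6 and scored 8.17 and 8.13 for the striatum. Cerebellum control 4 held 0 CPM of Gabra6 and 354.36 CPM of the hypothalamic gene Hcrt. These libraries were picked after their values were seen. Not all of the 14 stood out so, as cerebellum western 4 scored 3.85 for the striatum and 2.83 for the neocortex. No biological explanation was tested.

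The third pattern was Xist beside Y-linked transcripts in hippocampus control 5 and 6 and cerebellum western NaKtide 5. All 3 are close, cerebellum western NaKtide 5 being at a mean chi-square per gene of 3.67 and 5.87 from hippocampus control 6 and 5, and the same RNA in hippocampus control 5 and 6 is a candidate explanation, with a mean chi-square per gene of 2.45 against 7.69 for the next closest pair within a group. The same RNA in all 3 libraries, which that closeness would fit, is argued against by an Xist ratio of 3.59 of the cerebellum library to the others (95% interval 2.94 to 4.39, which covers counting error only), unless RNA of another library was carried over. Its log2 ratio of 1.84 compares with an SD of 0.20 over 5562 genes of similar count, of which 2, Xist included, had a ratio as large. RNA of a female and a male mouse mixed cannot be told apart from other sources, because Xist in cerebellum western NaKtide 5 was 23.6% of that in hippocampus western NaKtide 6 while its Y-linked sum of 39.1 CPM lay within the 19.1 to 70.3 CPM of 38 other libraries, and no biological explanation was tested.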

How the results depend on the processing

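Summing control 5 and 6, leaving out 4 libraries marked by Xist, length and GC offsets, the component covariate and thinning were chosen after seeing the data. Of the called genes, only those given by the naming rule were followed through the alternatives, 224 over all comparisons. They kept their direction in every alternative run for them but 1 case, Chordc1 for NaKtide on western diet in libraries labelled hippocampus (0.08 with length and GC offsets). The call was kept by 221 of 221 with an adjusted p in DESeq2, 222 of 224 with DESeq2 size factors, 171 of 224 with a replicate block and 129 of 224 with 2 surrogate variables. With length and GC offsets 56 of 79 kept it, and with the component covariate 55 of 79. Of 141 list calls 0 were kept with an estimated correlation, and 1 list reversed: cytosolic ribosomal protein genes, cerebellum: western vs control diet, with NaKtide (adjusted p = 0.000233 as reported, 0.00293 in the other direction with 2 surrogate variables, 0.00872 likewise without western NaKtide 3, and 8.55e-12 to 0.694 over single omissions, among them 0.116 and 0.694 without control NaKtide 4 and 5). Counts that moved over 1.5 times follow; the cause was not tested. DESeq2 called, in libraries labelled cerebellum, 142 genes for the diet without NaKtide, 1 for NaKtide on western diet, 1346 for NaKtide on control diet, 1 for the diet with NaKtide and 17 for the interaction, in libraries labelled hippocampus 825 for the diet without NaKtide, 12 for NaKtide on control diet, 33 for the diet with NaKtide and 183 for the interaction, and 1 for the region difference in the diet without NaKtide and 1709 for the region labels in control mice. Without a low-count filter cerebellum NaKtide on control diet gave 2, hippocampus diet without NaKtide 8, NaKtide on control diet 1 and diet with NaKtide 1, the region difference of NaKtide on western diet 794 and the region labels 11. With the compared groups only these were 60 for hippocampus diet without NaKtide, 719 for the region difference on western diet and 1 for the region labels. The replicate block gave 148 for the region labels and 5221 for hippocampus NaKtide on western diet (5542 as reported). With 2 surrogate variables hippocampus diet without NaKtide gave 2953, diet with NaKtide 1, interaction 35, the region difference on control diet 601 and the region labels 3. With control 5 and 6 summed hippocampus diet without NaKtide gave 39 and the region labels 5. Without the 4 libraries marked by Xist these gave 2209 and 3, and the region differences 1 for the diet without NaKtide and 503 for NaKtide on control diet. For hippocampus NaKtide on western diet length and GC offsets gave 3633. The component covariate gave 2076 there, 1015 for the diet without NaKtide, 80 for the diet with NaKtide and 38 for the interaction. Thinned to equal totals, which removes depth differences, cerebellum NaKtide on control diet gave 2 and the interaction 0. The reversal share in libraries labelled cerebellum was 80% with offsets, 100% for the 1 gene past the threshold and 48.9% with the western diet libraries divided, and in libraries labelled hippocampus 95% divided, with no gene past the threshold by edgeR to give a value there. Leaving out each library in turn, cerebellum counts ran 1 to 841 for the diet without NaKtide (2 without control 3, 841 without control 5), 0 to 1 for NaKtide on western diet (1 without western 1), 1 to 4386 for NaKtide on control diet (2 without control 3 or control NaKtide 1, 4386 without control 5) and 1 to 5 for the interaction (5 without control 5). Hippocampus counts ran 0 to 515 for the diet without NaKtide (28 without control 5, 515 without control 6, 345 without western 5), 0 to 1 for NaKtide on control diet (1 without control NaKtide 1, 2 or 5), 0 to 6 for the diet with NaKtide (1 without control NaKtide 1 or 5, 6 without western NaKtide 2), 0 to 59 for the interaction (47, 3 and 59 without control NaKtide 4, 5 and western NaKtide 2) and 3807 to 6116 for NaKtide on western diet, where no omission moved it over 1.5 times. The region difference of NaKtide on western diet ran 416 to 4089 (cerebellum western 1 691, 3 636, western NaKtide 1 575, 3 4089, 4 416, 5 730, hippocampus western 2 796, 3 780, 4 686, 5 2278, western NaKtide 1 794, 5 805) and on control diet 2020 to 5718 (cerebellum control 2 2065, 5 5718, control NaKtide 4 2290, 5 2020, hippocampus control NaKtide 4 2225). The region labels ran 1 to 4334 (cerebellum control 1 4, 2 1, 3 33, 4 7, 5 4334, hippocampus control 1 7, 2 194, 3 5, 4 2503, 5 6, 6 12). The cerebellum reversal share ran 66% to 93.5% (control 5 70.7%, western 1 93.5%, western NaKtide 2 82.5%, 3 66%).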

Other observations

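The relations below were chosen after the results were seen. Between independent groups of libraries labelled hippocampus, the fold changes of NaKtide on control diet and on western diet correlated at 0.37 across genes, and 14 of 80 shuffles of the group labels gave a correlation as large. The same relation in libraries labelled cerebellum was 0, with 80 of 80 shuffles as large. In libraries labelled cerebellum the diet responses with and without NaKtide correlated at -0.41, with 11 of 80 shuffles as large. In libraries labelled hippocampus these correlated at 0.04, with 74 of 80 as large. Relations between the region labels used differences of mean log2 of CPM plus 1 and 2000 shuffles of the group labels within each region label. Between the region labels the diet responses without NaKtide correlated at 0.55 (p = 0.045, adjusted p = 0.0675 over 3 relations), those to NaKtide on western diet at -0.08 (p = 0.798) and those to NaKtide on control diet at -0.55 (p = 0.0425, adjusted p = 0.0675). With edgeR fold changes the 3 correlations were 0.54, 0 and -0.49. None of these 3 relations between the labels passed 0.05 after adjustment.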
